A study of Arabidopsis thaliana with 16 samples.

How the data were processed

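Transcript levels in whole rosettes of Arabidopsis thaliana were measured on 16 Affymetrix arrays. The deposited table holds an intensity for each of 22810 probe sets, made by the authors with MAS5 per the submitters' processing notes, which give no version. The intensity values are on a linear scale with 1 decimal, and the mean of each array after trimming 2% at each end lay between 500.0 and 501.1, so each array had been scaled to a common mean. No other step between the arrays was found. The table holds no detection calls, so no probe set could be called absent, and array number limits the precision of every value.

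Samples were grouped by genotype, nitrate and harvest age as the labels give them, in 8 groups of 2 arrays. The labels give the high-nitrate arrays 2 different ages, 30 days in the titles and the design summary and 60 days in the source and description fields. They were kept as a group of their own, compared with low nitrate at 30 days, and compared with low nitrate at 60 days as an alternative. The replicate number marks the culture, so culture entered the fit as a block. This pairing was checked on the difference between the cultures, correlated across probe sets between groups. Over 28 pairs of groups r ran from -0.159 to 0.686 with a median of -0.0657, and 8 pairs were over 0.1. The criterion was an r over 0.1 in every pair, and it was not met. Genes are not independent replicates in these correlations. For culture itself 3 probe sets passed the threshold. The block was kept as the design gives it, and a fit without it is an alternative.

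The 64 control probe sets were left out of the tests. Signals under 1 were set to 1 and log2 was taken. Probe sets with a mean log2 signal under the 40th percentile of 22746 were left out, a limit that equals a geometric mean signal of 93.9, and 13648 were tested. limma 3.58.1 in R 4.3.3 was used, with lmFit and eBayes with a trend on 8 group means and the culture block, which left 7 residual degrees of freedom and a median of 4.64 prior degrees of freedom. The 15 comparisons were made as contrasts of this fit, two-sided, each adjusted by Benjamini-Hochberg over the 13648 probe sets, with a threshold of 0.05. The replicates behind every p are 2 cultures of pooled plants. Names ending in s_at or x_at mark probe sets that may bind transcripts of several related genes.

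Probe sets were named from a probe annotation that gives 1 gene to 13513 of them and several genes to 503, and does not list 8730. Among those tested, 7320 (53.6%) had 1 gene, 281 had several and 6047 were not listed, so counts cover all tested probe sets and names cover a part. No probe set is named for ATG5 or ATG9, so the mutated genes themselves were not analysed here. Genes named in the text followed a rule. Per comparison it took, among probe sets past the threshold with 1 gene and the same direction in both cultures, up to 10 with the largest rise and 10 with the largest fall, and up to 4 members of each fixed list by smallest p. For interactions and for atg9 against atg5 up to 5 per direction were taken, and where none passed, the 5 probe sets with the smallest p were given as values. Members of the named set were followed into the other comparisons of the mutants. The rule put ATG5 and ATG9 first, which have no named probe set here. Where several probe sets name 1 gene, that with the highest mean signal was used. Probe sets without a gene name that passed, list members that did not pass, and genes of the 8 later lists were chosen after their values were seen.

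Gene lists were written before the data were examined, as were the contrasts, the named-gene rule and the alternatives, except where a choice is said to be later. There were 16 lists with 384 members. A symbol check against the annotation kept 373 and dropped 11, and 70 had a named probe set, of which 61 were tested. The 9 lists with at least 3 tested members were autophagy, salicylic acid and defence, senescence, vacuolar and other proteases, proteasome, photosynthesis, flavonoid and anthocyanin, glucosinolate and sulfate assimilation, and abscisic acid, cold and dehydration. Those with 2 tested members, given as single genes, were jasmonate and ethylene defence, nitrate transport and nitrogen assimilation, oxidative stress and glutathione transferases, and ER protein folding. The root list had 1 tested member, and the floral and bolting and heat shock chaperone lists had 0. The lists were tested with camera at a preset correlation of 0.01, adjusted over 135 tests, of which 46 passed. With a correlation estimated from the data, 0 of these 46 passed. Tests by fry, which asks whether a set moves on balance in a single direction and does not compare it with other genes, are given beside some lists. A further 8 lists of gene families and organelle genomes, tested as a family of 120, were chosen after the data were seen.

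The procedure was tested on simulated data with 13648 probe sets, noise as in the arrays and 50 changed probe sets per size. For the comparison of atg5 with Col-0 at 30 days it recovered 8 at a log2 change of 1, 36 at 2, 49 at 4 and 50 at 6, with 7 false calls among the unchanged. For the comparison at 60 days it recovered 10 at 1, 38 at 2, 50 at 4 and 49 at 6, with 5 false calls. At an unadjusted p under 0.05, camera called all 20 simulated lists of 10 probe sets shifted by 1 in each comparison. It called 1 of the unshifted lists in each. These lists were drawn at random with noise independent between probe sets. The simulation therefore cannot show how camera does with correlated genes or after adjustment.

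Comparisons that share an array also share its error. Correlations between their effects, across probe sets, are given with values from 100 simulated sets of unchanged arrays and with values across cultures that share no array. A slope of an effect on another is their covariance over arrays they do not share, divided by the covariance of the latter between the 2 cultures. The alternatives were a fit without the culture block, quantile normalization between arrays, no filter on dim probe sets, log2 of the signal plus 32, eBayes without the trend, low nitrate at 60 days in place of 30 days, an estimated correlation for the lists, and leaving out each array in turn. A fit without 2 arrays that stand apart was added after the data were seen. Groups of 2 are too small for a test of single outlying arrays or of other splits of the samples.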

Results

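Whole Arabidopsis rosettes were profiled on 16 arrays in 8 groups of 2. Col-0 is the wild type, and atg5 and atg9 are mutants in genes of autophagy, the pathway that carries cytoplasm to the vacuole for breakdown. Plants grew in short days with 8 h of light and 16 h of dark, on low nitrate (LN, 2 mM) or high nitrate (HN, 10 mM), and each array held a pool of more than 6 plants. The 3 genotypes were harvested on low nitrate at 30 days (T30) and 60 days (T60), and Col-0 and atg5 also on high nitrate. The labels give the high-nitrate arrays as both 30 and 60 days old. Each group had 1 array from each of 2 cultures grown months apart, so n = 2 per group throughout. Changes are log2 differences, with the SE of limma's fit after ±, and signals are linear intensities. A change with 32 added to the signals is given where a group had signals under the lower quartile of its arrays. It is a damped estimate of the size and not a strict bound on it.

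The median signal per array ran from 154 to 254. The array of Col-0 at 30 days from culture 1 had a lower quartile of 89.3, against 26.6 to 39.0 in the other 15, and correlated with its replicate at r = 0.869 across probe sets. The array of atg5 at 60 days from culture 1 had a 3′/5′ signal ratio of 9.05 for the actin control, against 1.5 to 3.04 in the others, and of 2.01 for GAPDH, against 0.782 to 1.24. It correlated with its replicate at r = 0.902, and the other 6 groups did so at 0.933 to 0.964. A high 3′/5′ ratio is a mark of degraded RNA.

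**Figure D1:**
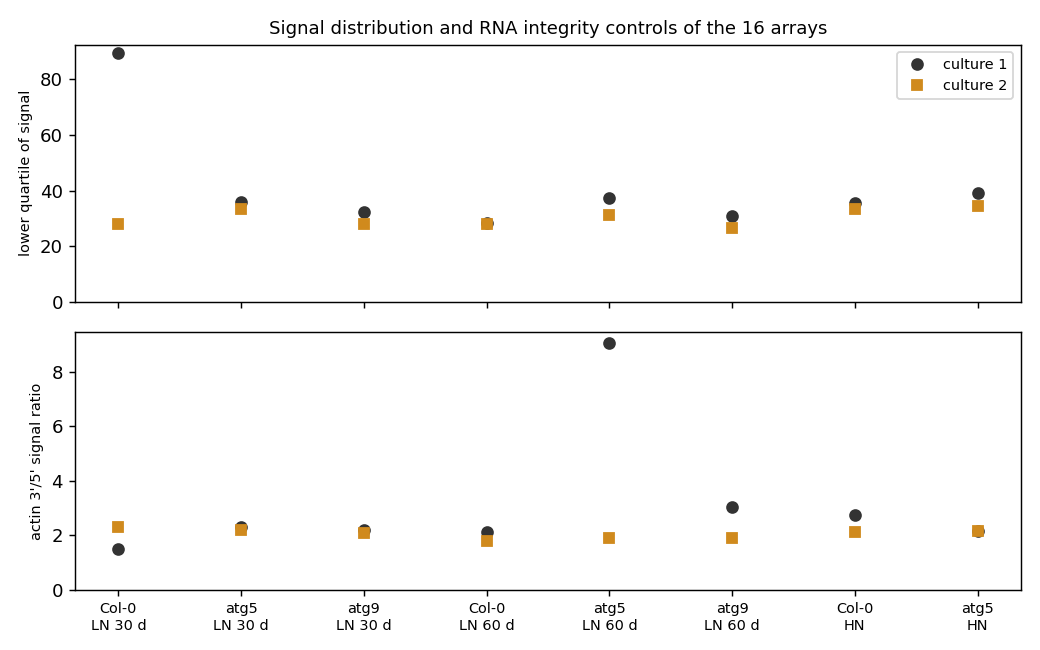
Lower quartile of the signal (top, linear intensity) and ratio of 3′ to 5′ actin control signals (bottom) for each array, by group and culture (circles, culture 1; squares, culture 2). The Col-0 array of culture 1 at 30 days sits at 89.3 in the top panel, and the atg5 array of culture 1 at 60 days at 9.05 in the bottom panel.

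At 60 days on low nitrate, the comparison of atg5 with Col-0 asked which transcripts differ in older rosettes when autophagy is blocked. ATG8H, for a ubiquitin-like protein of the autophagosome, rose by 4.05 ± 0.44 in atg5 (adjusted p = 0.0019). AT3G47540, of the chitinase family, rose by 4.23 ± 0.26 (adjusted p = 2.57e-05), and a chitinase gene named CHI here (AT2G43570) by 5.79 ± 0.91. The largest rises among named genes were AT1G05340 at 6.27 ± 0.85 and AT1G26390, of the berberine bridge enzyme family, at 6.04 ± 0.78. The receptor kinase gene AT1G51890 rose by 5.49 ± 1.00 (4.23 with 32 added), AT5G40690 by 5.10 ± 0.54, and SARD4, for an enzyme of pipecolic acid synthesis, by 3.22 ± 0.47. Among the falls, AT1G78450 changed by -3.22 ± 0.46 (-2.58 with 32 added), the cold-regulated COR15B by -2.03 ± 0.35, the expansin gene EXPB3 by -2.32 ± 0.58 and the plastid-encoded ribosomal gene rpl14 by -2.47 ± 0.46. In the fit lacking the 2 arrays that stand apart, COR15B (-1.95, adjusted p = 0.0749), EXPB3 (-1.18, adjusted p = 0.325) and rpl14 (-2.05, adjusted p = 0.105) did not pass.

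Of the 16 autophagy genes tested, 5 rose in atg5 at 60 days, 0 fell and 11 did not pass, and 11 were higher when adjusted over the list alone. The 5 were ATG8H, ATG8E (2.7 ± 0.45), ATG14A (2.23 ± 0.58), ATG8A (1.54 ± 0.25) and ATG1A (1.29 ± 0.25), while ATG1C lay at -0.27. The list median was 0.65, at 0.82 in culture 1 and 0.45 in culture 2, and the list was higher than other genes by camera (adjusted p = 4.95e-09, and adjusted p = 0.277 with an estimated correlation). By fry it moved up (adjusted p = 0.0057). After removal of the 2 arrays that stand apart, ATG8H (3.42) and ATG8A (1.6) passed and the median was 0.64.

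Among 4 salicylic acid and defence genes, SARD4 rose, and WRKY53 (2.77), GRX480 (2.26) and SAG101 (0.93) did not pass over all genes. With SARD4, 2 of the 4 passed when adjusted over the list alone, and the list was higher (adjusted p = 0.00235, and adjusted p = 0.47 with an estimated correlation). The 3 senescence genes, SWEET15 (2.44), WRKY6 (1.38) and PPDK (1.11), gave 0 passing over all genes and 3 over the list alone (list adjusted p = 0.0125, and adjusted p = 0.362 with an estimated correlation). The flavonoid and anthocyanin genes UF3GT (-3.78), UGT75C1 (-3.66), DFR (-3.35), 5MAT (-2.76) and UGT78D2 (-0.44) gave 0 passing over all genes and 4 over the list alone. Their list was lower (adjusted p = 0.0381, and adjusted p = 0.571 with an estimated correlation), and it did not pass without the culture block (adjusted p = 0.0599). The median of these 5 was -4.89 in culture 1, the culture of the atg5 array with the high actin ratio, and -1.91 in culture 2, and -1.37 without the 2 arrays that stand apart.

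Of 4 abscisic acid, cold and dehydration genes, COR15B fell and COR15A (-2.87), LTI30 (-0.69) and COR47 (-0.28) did not pass, and 0 of the 4 passed without the 2 arrays that stand apart. In atg5 at 60 days 0 members changed among 6 photosynthesis genes (median -0.18), 6 proteasome genes (-0.11), 5 protease genes (-0.05) and 3 glucosinolate and sulfate genes (-1.06). The medians of the protease and proteasome lists lay below 0 while camera placed both lists up (adjusted p = 0.957 and 0.984). NRT2.5 for a nitrate transporter (1.05), PDF1.2 for a plant defensin (-1.11), BZIP60 (1.03), NDB2 (0.91), UPOX (-0.36) and ERDJ3B (0.69) did not pass either, nor did the root marker BGLU23 (0.07).

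By limma's test 541 probe sets were higher and 254 lower in atg5 than in Col-0 at 60 days. Of these, 238 and 123 were named. All 795 went in the same direction in both cultures, as did every probe set called in the other comparisons. The threshold leaves little room for opposite directions in 2 cultures, so this is no separate support. The count was 100 without the Col-0 array of culture 1, 196 without that of culture 2, 196 without the atg5 array of culture 1 and 1647 without that of culture 2. Without the 2 arrays that stand apart it was 232, with 212 higher and 20 lower, and 12 of 26 named genes kept their call. Of the 26, 5 kept it without each of these arrays, and 21 lost it without the Col-0 array of culture 1. EXPB3 (adjusted p = 0.116) and AT3G17640 (-3.06 ± 0.78, adjusted p = 0.0618) did not pass without the culture block, and AT5G15780 (-2.43 ± 0.63) did not after quantile normalization (adjusted p = 0.0816). With 32 added AT3G17640 lay at -1.92 and passed, and AT5G15780 lay at -1.66 and did not (adjusted p = 0.0579). With the 2 arrays that stand apart left out, AT3G17640 (-1.37, adjusted p = 0.306) and AT5G15780 (-1.91, adjusted p = 0.322) did not pass either.

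**Figure D2:**
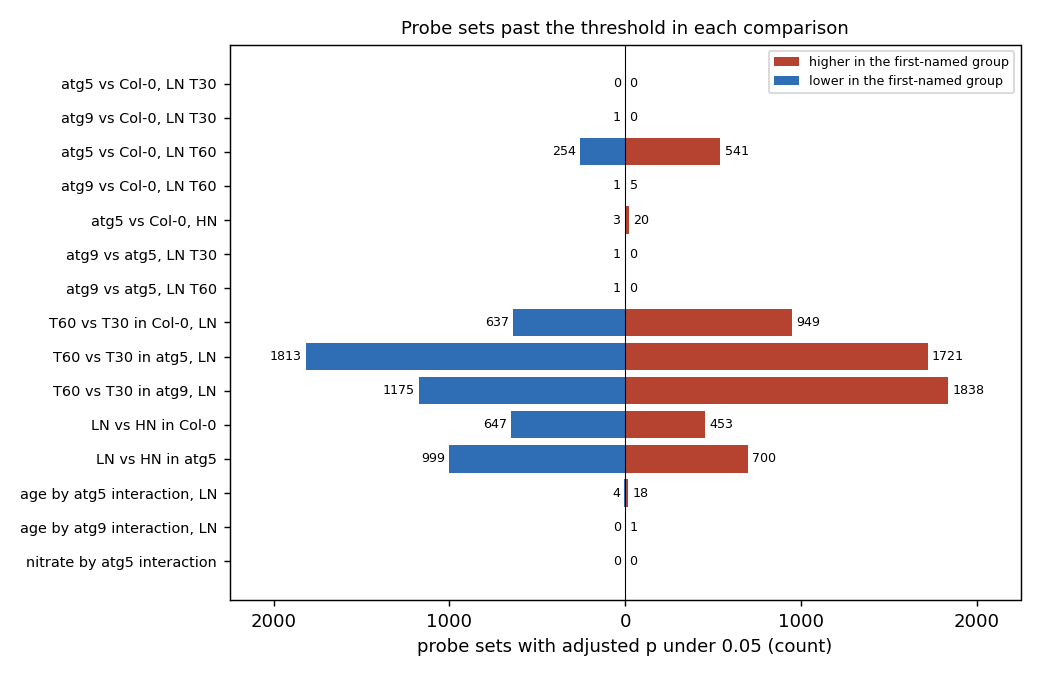
Number of probe sets with an adjusted p under 0.05 in each comparison, higher (right) or lower (left) in the first-named group; LN and HN are low and high nitrate, T30 and T60 the harvest days, and interactions are differences of differences. The comparison of atg5 with Col-0 at 60 days gave 541 and 254, and that of atg9 gave 5 and 1.

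In atg9 at 60 days AT3G47540 rose by 3.19 ± 0.26 against Col-0 (adjusted p = 0.000292), AT5G40690 by 3.94 ± 0.54 (adjusted p = 0.0422) and AT3G47480, for an EF-hand protein, by 3.69 ± 0.53 (adjusted p = 0.0448). ATG8H lay at 2.18 ± 0.44 (adjusted p = 0.0904), ATG8E at 1.66 ± 0.45 and ATG8A at 0.75 ± 0.25, none of which passed. The probe sets without a gene name, chosen after their values were seen, were 266270_at (5.78 ± 0.77, and 3.95 with 32 added) and 261934_at (3.08 ± 0.45), which rose, and 264113_at (adjusted p = 0.000246), which was lower. Its atg9 signals were too near background for the size to be measured. The difference with 32 added, a damped estimate of the size, was -3.09 (adjusted p = 0.00484). In the fit without the 2 arrays that stand apart, which are in neither group, AT3G47540 and 264113_at passed and AT5G40690, AT3G47480, 266270_at and 261934_at did not (adjusted p = 0.0547 in each, with the same log2 changes).

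Of the 16 autophagy genes 0 passed over all genes in atg9 at 60 days and 2 when adjusted over the list alone, with a median of 0.37 (list higher, adjusted p = 1.01e-06, and adjusted p = 0.361 with an estimated correlation). The 4 salicylic acid and defence genes had a median of 1.52 with 0 passing (list adjusted p = 0.000916, and adjusted p = 0.439 with an estimated correlation). The 5 flavonoid genes had a median of -1.42 with 0 passing (list adjusted p = 0.0278, and adjusted p = 0.571 with an estimated correlation), and the 4 cold and dehydration genes one of -0.76 (list adjusted p = 0.0295, and adjusted p = 0.555 with an estimated correlation). By limma's test 5 probe sets were higher and 1 lower, with 642 under an unadjusted p of 0.05 where 682 would be expected if none changed. The count was 2 without either atg9 array, 3 without the Col-0 array of culture 2 and 4 without that of culture 1. It was 36 without the culture block, 61 after quantile normalization, 28 with no filter on dim probe sets, 56 on the log2 scale with 32 added, 3 without the trend and 4 without the 2 arrays that stand apart.

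Effects of atg5 and atg9 at 60 days, which share their Col-0 arrays, correlated at r = 0.871 over 13648 probe sets, against 0.501 in unchanged simulated arrays, with a covariance of 0.388 against 0.0752. Taken across cultures that share no array, r was 0.574 and 0.760, and the slope of atg9 on atg5 was 0.490 and 0.646. All 5 probe sets higher in atg9 were among the 541 higher in atg5, where 0.198 would be shared by independent lists. Unchanged groups with a shared control were also simulated in 100 sets and ranked by size, without a test. Of the 5 largest rises of the second group, 2.59 on average and at most 5 were among the 541 largest of the first. Genes are not independent replicates in these correlations.

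**Figure D3:**
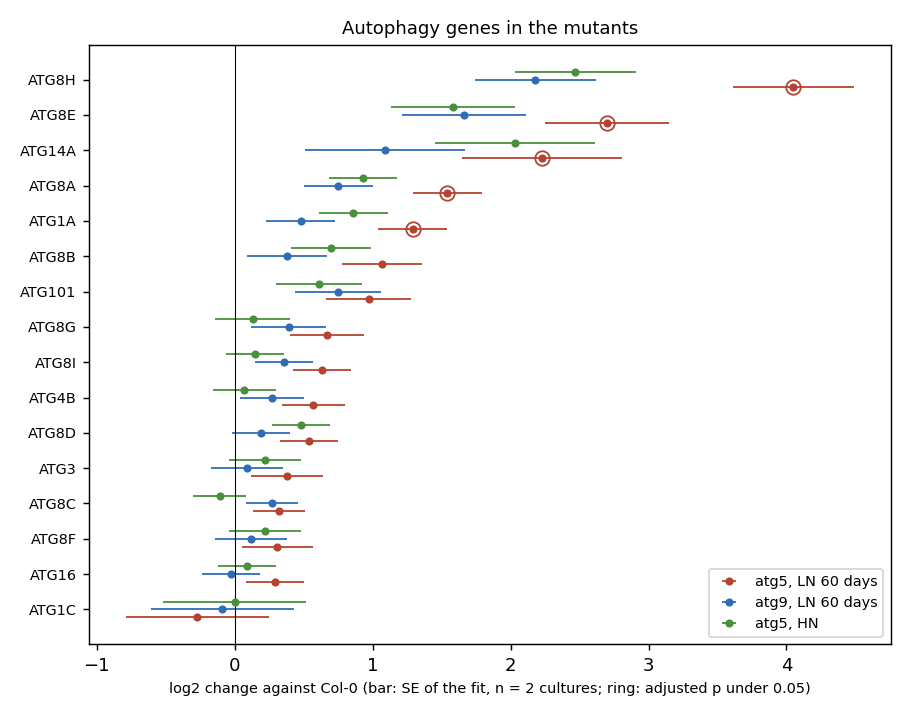
Change of 16 autophagy genes against Col-0 (log2, points, with the SE of the fit as bars, n = 2 cultures) in atg5 and atg9 at 60 days on low nitrate and in atg5 on high nitrate; rings mark an adjusted p under 0.05. The 5 rings are all in atg5 at 60 days, where ATG8H rose by 4.05, with 2.18 in atg9 and 2.47 in atg5 on high nitrate.

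On high nitrate AT1G62760, of the pectin methylesterase inhibitor family, rose by 5.26 ± 0.71 in atg5 against Col-0 (adjusted p = 0.0269), AT1G05340 by 5.02 ± 0.85 and AT2G37750 by 4.38 ± 0.58. The proline dehydrogenase gene AT5G38710 rose by 3.87 ± 0.56, AT5G40690 by 3.76 ± 0.54 and AT3G47540 by 1.89 ± 0.26. MSRB5, for a methionine sulfoxide reductase, fell, at -1.85 ± 0.28 (adjusted p = 0.0308). ATG8H lay at 2.47 ± 0.44 (adjusted p = 0.0598), PDF1.2 at 1.94 ± 0.79 and PDF1.2B at 2.51 ± 0.81, and none of the 3 passed. In the fit without the 2 arrays that stand apart ATG8H passed (adjusted p = 0.045) and AT1G05340 did not (adjusted p = 0.0706), with the same log2 changes.

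Of the 16 autophagy genes 0 passed over all genes in atg5 on high nitrate and 5 when adjusted over the list alone, with a median of 0.35 (list higher, adjusted p = 7.4e-06, and adjusted p = 0.361 with an estimated correlation). The 5 flavonoid genes, from UF3GT and DFR at -2.97 to UGT78D2 at -1.64, gave 0 passing over all genes and 5 over the list alone (list lower, adjusted p = 0.000151, and adjusted p = 0.384 with an estimated correlation). Their median was -2.26 in culture 1 and -3.54 in culture 2. The salicylic acid and defence genes had a median of 1.82 (list adjusted p = 0.00235, and adjusted p = 0.47 with an estimated correlation), the senescence genes one of 0.86 (list adjusted p = 0.0183, and adjusted p = 0.384 with an estimated correlation), and 0 of either passed. The 6 photosynthesis genes had a median of -0.27 with 0 passing (list adjusted p = 0.0426, and adjusted p = 0.594 with an estimated correlation), and the list did not pass after quantile normalization (adjusted p = 0.199).

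By limma's test 20 probe sets were higher and 3 lower in atg5 on high nitrate, and 1099 had an unadjusted p under 0.05. The count was 0 without the Col-0 array of culture 1 or the atg5 array of culture 2, and 43 without the Col-0 array of culture 2, and 0 of 9 named genes kept their call without each array. It was 63 after quantile normalization, 62 on the log2 scale with 32 added, 14 without the trend and 47 without the 2 arrays that stand apart, which are in neither group. All 20 higher probe sets were also higher in atg5 at 60 days on low nitrate (0.793 expected of independent lists), as were 2 of the 3 lower (0.0558 expected), and the effects, which share no array, correlated at r = 0.797.

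At 30 days on low nitrate 0 probe sets passed limma's test between atg5 and Col-0. An unadjusted p under 0.05 was found in 960, where 682 would be expected if none changed. The named gene with the smallest p was AT1G57630, for a protein with a TIR domain, (adjusted p = 0.221), at 1.96 on the log2 scale with 32 added. The other 4 by smallest p, probe sets without a single gene name, were 246927_s_at at 1.89 and 260567_at at 1.69, both with 32 added, 247874_at at 1.21 and 250088_at at -2.24. ATG8H lay at 0.01, AT3G47540 had a mean log2 signal of 8.73 in atg5 and 8.77 in Col-0, and the 16 autophagy genes had a median of -0.06. The 6 photosynthesis genes had a median of 0.31 (list higher, adjusted p = 0.0381, and adjusted p = 0.59 with an estimated correlation), at 0.06 without the 2 arrays that stand apart, and the list did not pass after quantile normalization (adjusted p = 0.0539). The count stayed at 0 without the Col-0 array of culture 1, and it was 766 without the Col-0 array of culture 2, when the array with the raised lower quartile stood alone for Col-0.

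In atg9 at 30 days 1 probe set, 264113_at, was lower than in Col-0 (adjusted p = 0.00233). Its difference with 32 added, a damped estimate of the size, was -2.84 (adjusted p = 0.0349), and 810 had an unadjusted p under 0.05. The count was 0 without the Col-0 array of culture 1 or the atg9 array of culture 2, and 874 without the Col-0 array of culture 2. In the fit lacking the 2 arrays that stand apart, 264113_at did not pass (adjusted p = 0.0586). The photosynthesis genes had a median of 0.27 with 0 passing (list higher, adjusted p = 0.0391, and adjusted p = 0.59 with an estimated correlation). The median was 0.63 in culture 1, the culture of the Col-0 array with the raised lower quartile, and -0.13 in culture 2, where 5 of the 6 were lower. It was 0.02 without the 2 arrays that stand apart, and the list did not pass after quantile normalization (adjusted p = 0.0844). Effects of atg5 and atg9 at 30 days correlated at r = 0.772, against 0.501 in simulated unchanged arrays (covariance 0.169 against 0.0752), and at -0.0474 and 0.00451 across cultures that share no array.

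In the direct comparison of the mutants 264113_at was lower in atg9 than in atg5 at 30 days (adjusted p = 0.00834) and at 60 days (adjusted p = 2.64e-05). Its signals in the 4 atg9 arrays ran from 1.9 to 6.9, under the lower quartile of every array (26.6 or more), and its mean was between 155 and 773 in the other 6 groups. The size of the difference was therefore not measured, and only a damped estimate is given. With 32 added it was -2.31 at 30 days, which did not pass (adjusted p = 0.27), and -4.47 at 60 days (adjusted p = 0.000264). It has no gene name here, so whether it measures ATG9 was not determined. By limma's test it was the 1 probe set passing at each age, with 149 and 1079 under an unadjusted p of 0.05. At 30 days the count was 0 without any 1 of the 4 arrays and on the log2 scale with 32 added. At 60 days it was 144 without the atg5 array of culture 2, which leaves the array with the high actin ratio, and 3 after quantile normalization. The autophagy list was lower in atg9 than in atg5 at 60 days (median -0.31, adjusted p = 1.09e-07, and adjusted p = 0.332 with an estimated correlation), as were the salicylic acid and defence list (median -1.0, adjusted p = 0.0391, and adjusted p = 0.571 with an estimated correlation) and the senescence list (median -0.89, adjusted p = 0.0101, and adjusted p = 0.361 with an estimated correlation). At 30 days the senescence list was lower (median -0.79, adjusted p = 0.0276, and adjusted p = 0.438 with an estimated correlation), though not after quantile normalization (adjusted p = 0.0801).

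From 30 to 60 days in Col-0 on low nitrate, AT4G16260, of the beta-1,3-glucanase family, rose (adjusted p = 0.000399). Its signals at 30 days, 20.3 and 8.3, lay under the lower quartiles of their arrays. Only a damped estimate of the size is therefore given, 4.55 with 32 added. Rises were also seen in the plant defensin genes PDF1.2 and PDF1.2B, of 5.80 ± 0.79 and 5.54 ± 0.81. The linker histone gene HIS1-3 rose by 4.31 ± 0.54 and AT3G23550, for a MATE efflux protein, by 4.11 with 32 added, its 30-day signals being under the lower quartiles too. AT1G13650 fell (-5.14 with 32 added), as did AT1G49500 (-4.93 ± 0.64), the thionin gene THI2.2 (-3.50 ± 0.45) and AT1G62510, of the lipid transfer protein family (-4.02 ± 0.54). With 32 added AT4G16260 rose by 4.58 in atg5 and 4.80 in atg9, and AT1G13650 changed by -5.15 and -5.68 there. The defensin genes PDF1.2 (3.15 and 5.72) and PDF1.2B (3.31 and 5.87) rose in atg5 and atg9 as well. AT1G57630 rose in Col-0 (adjusted p = 0.0075), from 30-day signals under the lower quartiles, but with 32 added it lay at 1.49 and did not pass (adjusted p = 0.0879). After removal of the 2 arrays that stand apart, AT1G57630 in Col-0 (adjusted p = 0.0661) and PDF1.2B in atg5 (3.35, adjusted p = 0.0718) did not pass. Of the named genes, 14 of 31 named genes in Col-0, 34 of 45 in atg5 and 40 of 41 in atg9 kept their call in that fit.

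Protease genes rose with age. Of 5, 4 rose in Col-0, 3 in atg5 and 4 in atg9, and 0 fell. CATHB3, for a cathepsin B-like protease, rose by 1.67, 2.07 and 2.19 in these genotypes, CATHB2 by 1.19, 1.09 and 1.13, and GAMMA-VPE, for a vacuolar processing enzyme, by 1.97, 1.5 and 2.17. BETA-VPE rose by 2.31 and 2.26 in Col-0 and atg9 and lay at 0.77 in atg5. The list was higher with age in Col-0 (adjusted p = 0.00124, and adjusted p = 0.362 with an estimated correlation) and in atg9 (adjusted p = 0.00704, and adjusted p = 0.452 with an estimated correlation). Without the 2 arrays that stand apart BETA-VPE passed in Col-0, and CATHB3 (1.3, adjusted p = 0.0671), CATHB2 (0.81, adjusted p = 0.0903) and GAMMA-VPE (1.08, adjusted p = 0.0677) did not. In atg5 BETA-VPE lay at 1.96 and passed (adjusted p = 0.0322). Of 3 senescence genes, WRKY6 (1.49, 2.37 and 1.99) and PPDK (1.36, 2.14 and 2.05) rose in the 3 genotypes and SWEET15 (-1.17, -0.84 and -1.07) did not pass. With 32 added WRKY6 rose by 0.99 in Col-0. There WRKY6 (1.52, adjusted p = 0.0731) and PPDK (0.97, adjusted p = 0.108) did not pass without the 2 arrays, and WRKY6 did not after quantile normalization (adjusted p = 0.115).

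Autophagy genes rose with age, 2 of 16 in Col-0, 15 in atg5 and 12 in atg9. ATG8D rose by 1.28 ± 0.21, 1.86 ± 0.21 and 1.7 ± 0.21, and ATG8B by 1.43 ± 0.29, 2.54 ± 0.29 and 1.7 ± 0.29. ATG8H rose by 3.60 in atg5 and 1.87 in atg9 and lay at -0.43 in Col-0. The medians were 0.43, 1.58 and 1.23, and the list was higher in Col-0 (adjusted p = 0.0219, and adjusted p = 0.555 with an estimated correlation), in atg5 (adjusted p = 2.8e-09, and adjusted p = 0.277 with an estimated correlation) and in atg9 (adjusted p = 3.82e-06, and adjusted p = 0.361 with an estimated correlation). With the 2 arrays that stand apart left out, 1, 11 and 13 of the 16 rose, and ATG8B did not pass in Col-0 (1.43, adjusted p = 0.0701).

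The glucosinolate genes UGT74B1 (-1.11, -1.28 and -1.06) and UGT74C1 (-1.14, -2.12 and -1.79) fell with age in Col-0, atg5 and atg9, and BCAT4 fell in atg5 (-2.76 ± 0.64). Their list was lower in Col-0 (adjusted p = 0.0276), atg5 (adjusted p = 0.0183) and atg9 (adjusted p = 0.0278), with an adjusted p = 0.555 with an estimated correlation in each. UGT74B1 and UGT74C1 did not pass in Col-0 without the culture block (adjusted p = 0.0794 and 0.0599), nor UGT74B1 in atg9 (adjusted p = 0.0655), nor the list in atg9 after quantile normalization (adjusted p = 0.0676). In the fit lacking the 2 arrays that stand apart, 0 of the 3 fell in Col-0 (UGT74B1 -0.98, adjusted p = 0.179, UGT74C1 -1.16, adjusted p = 0.133). In atg5 UGT74C1 fell (-1.83) while UGT74B1 (-1.18, adjusted p = 0.085) and BCAT4 (-1.95, adjusted p = 0.113) did not pass. Of 6 photosynthesis genes 0 changed in Col-0, SBPASE (-1.10) and ATPC1 (-0.74) fell in atg5, and SBPASE (-1.10) and PRK (-0.76) fell in atg9, with lists lower in atg5 (adjusted p = 0.0278, and adjusted p = 0.59 with an estimated correlation) and atg9 (adjusted p = 0.0154, and adjusted p = 0.571 with an estimated correlation). After removal of the 2 arrays that stand apart, 0 of the 6 fell in atg5, with SBPASE at -0.93 (adjusted p = 0.0591) and ATPC1 at -0.75 (adjusted p = 0.123). After quantile normalization ATPC1 in atg5 (-0.29), PRK in atg9 (-0.33) and the lists in atg5 (adjusted p = 0.186) and atg9 (adjusted p = 0.315) did not pass.

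COR15B fell with age in atg5 (-2.24 ± 0.35) and atg9 (-1.23 ± 0.35), COR15A in atg5 (-2.68 ± 0.88, with adjusted p = 0.0552 without the culture block, and -1.35 with adjusted p = 0.395 without the 2 arrays that stand apart), and 0 of the 4 genes of that list changed in Col-0. SARD4 and SAG101 of the salicylic acid list rose in atg5 (2.11 and 1.27) and SAG101 in atg9 (1.61), though SAG101 did not pass in atg5 without the culture block (adjusted p = 0.0735), and 0 changed in Col-0. The 5 flavonoid genes (medians 1.29, -1.33 and 0.72) and the 6 proteasome genes (0.09, -0.07 and -0.11) gave 0 changed in each genotype, and the flavonoid median turned between the cultures in atg5 (-4.27 in culture 1, 1.31 in culture 2) and in atg9 (-1.62 and 3.07). NRT2.5 rose in atg5 (4.06 ± 0.81) and atg9 (4.73 ± 0.81), by 3.16 and 3.59 with 32 added, and lay at 1.83 in Col-0, and HHO2, a regulator of nitrate and phosphate responses, fell in the 3 genotypes (-1.40, -1.25 and -1.47). Without the 2 arrays that stand apart NRT2.5 also rose in Col-0 (3.06, adjusted p = 0.0376), and HHO2 did not pass there (-1.10, adjusted p = 0.0899). BZIP60 (1.51 and 1.40) and NDB2 (1.73 and 1.09) rose in atg5 and atg9, and NDB2 did not pass in atg9 after quantile normalization (adjusted p = 0.0897). The root marker BGLU23 fell in atg5 (-1.21, and -1.17 with adjusted p = 0.123 without the 2 arrays) and atg9 (-1.64) and lay at -1.13 in Col-0.

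**Figure D4:**
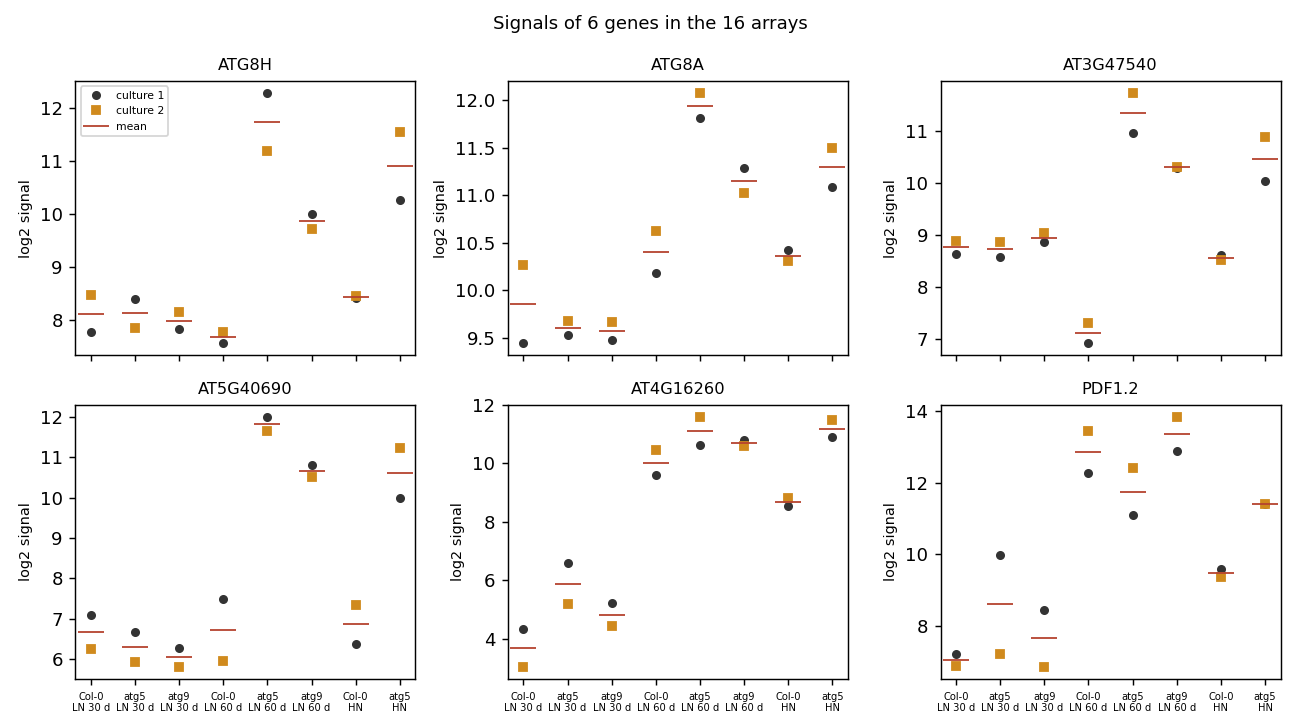
Log2 signals of 6 genes in each array (circles, culture 1; squares, culture 2; lines, means of 2), by genotype, nitrate (LN low, HN high) and day. Mean ATG8H was 11.73 in atg5 and 7.69 in Col-0 at 60 days and 8.13 and 8.12 at 30 days, and mean AT4G16260 in Col-0 was 3.70 at 30 days (under the lower quartile of both arrays), 10.02 at 60 days and 8.69 on high nitrate.

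By limma's test 949 probe sets rose and 637 fell with age in Col-0, 1721 rose and 1813 fell in atg5, and 1838 rose and 1175 fell in atg9. Of those rising in Col-0, 680 also rose in atg9 (128 expected) and 458 in atg5 (120 expected), and of those falling 502 and 441 fell (54.8 and 84.6 expected), in comparisons with no array in common. In Col-0 the count was 289 without the 30-day array of culture 1, 2546 without that of culture 2, 67 without the 60-day array of culture 1 and 576 without that of culture 2, and 9 of 31 named genes kept their call throughout. In atg5 the count was 1792 and 1017 without the 30-day arrays of cultures 1 and 2 and 1521 without the 60-day array of culture 1, and 27 of 45 named genes kept their call. In atg9 it was 1599, 832, 794 and 1589 without the 30-day arrays of cultures 1 and 2 and the 60-day arrays of cultures 1 and 2, and 23 of 41 kept it. With the 2 arrays that stand apart left out, the count was 369 in Col-0, 2016 in atg5 and 4078 in atg9. Quantile normalization moved the median change of all probe sets in atg9 from 0.125 to -0.026. The share that rose in atg9 was then 48.1% in place of 61.0%, and 49.2% in place of 59.8% in Col-0.

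The difference between genotypes in the change with age was tested directly. AT3G47540 fell with age in Col-0 (-1.65 ± 0.26) and rose in atg5 (2.62 ± 0.26) and atg9 (1.34 ± 0.26). It kept these 3 calls without the 2 arrays that stand apart. The change was 4.26 ± 0.36 higher in atg5 than in Col-0 (adjusted p = 0.00106) and 2.99 ± 0.36 higher in atg9 (adjusted p = 0.0432). In atg5 the change was also higher for ATG8H (4.04 ± 0.62), AT5G40690 (5.47 ± 0.77), AT2G15220 (5.71 ± 0.90, and 4.59 with 32 added) and AT5G38900 (5.07 ± 0.85), and lower for AT1G68490 (-1.95 ± 0.32), each with an adjusted p = 0.0498. The first 4 rose with age in atg5 (3.60, 5.52, 4.85 and 4.2) and did not pass in Col-0 (-0.43, 0.05, -0.86 and -0.87). They rose with age in atg9 too (1.87, 4.61, 3.42 and 3.82). AT1G68490 rose in Col-0 (1.56) and did not pass in atg5 (-0.39). The change of the autophagy list was higher in atg5 (median 0.95, adjusted p = 3.83e-09, and adjusted p = 0.277 with an estimated correlation), with 1 member passing over all genes and 9 over the list alone, and in atg9 (median 0.57, adjusted p = 1.31e-05, and adjusted p = 0.361 with an estimated correlation). The salicylic acid and defence list was higher in both (adjusted p = 0.02 and 0.0106, and adjusted p = 0.555 with an estimated correlation in each). In the fit lacking the 2 arrays that stand apart, AT3G47540 passed for atg5 (4.51, adjusted p = 0.0378) and not for atg9 (2.98, adjusted p = 0.383). ATG8H (3.68), AT5G40690 (5.02), AT5G38900 (4.46) and AT1G68490 (-1.74), with an adjusted p = 0.302 in each, and AT2G15220 (5.5, adjusted p = 0.316) did not pass.

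In limma's test 18 probe sets were higher and 4 lower in the difference for atg5, with 1953 under an unadjusted p of 0.05, and 1 higher in that for atg9, with 630. For atg5 the count was 1 without the 30-day Col-0 array of culture 1, either 30-day atg5 array, the 60-day Col-0 array of culture 2 or the 60-day atg5 array of culture 1. It was 3 without the 60-day Col-0 array of culture 1, 207 without the 60-day atg5 array of culture 2 and 689 without the 30-day Col-0 array of culture 2. It was 38 without the culture block, 123 after quantile normalization, 56 with no filter, 86 with 32 added and 1 without the trend or without the 2 arrays that stand apart. For atg9 it was 337 without the 30-day Col-0 array of culture 2 and 0 without any other array of the comparison, and AT3G47540 did not pass without the culture block (adjusted p = 0.19), after quantile normalization (adjusted p = 0.0938) or with 32 added (adjusted p = 0.0677).

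Low nitrate at 30 days was compared with high nitrate, a comparison in which nitrate and age cannot be told apart because the labels give 2 ages for the high-nitrate arrays. In Col-0 the thionin gene THI2.2 was higher on low nitrate (4.04 ± 0.45, adjusted p = 0.000993), as were SP1L4 (3.73 ± 0.67, and 2.99 with 32 added) and EXO (2.63 ± 0.44). AT4G16260 was lower (adjusted p = 0.000993), as were HIS1-3 (-4.81 ± 0.54), the osmotin gene OSM34 (adjusted p = 0.0115), CHI (-4.16 ± 0.91, and -3.39 with 32 added) and AT1G57630 (adjusted p = 0.00197). In AT4G16260, OSM34 and AT1G57630 the low-nitrate signals lay under the lower quartiles of both arrays. The damped estimates of the size were -3.28, -2.8 and -2.63 with 32 added. On low nitrate at 60 days mean log2 AT4G16260 in Col-0 was 10.02, above the 8.69 on high nitrate. In atg5 it was 11.11, near the 11.19 on high nitrate. After removal of the 2 arrays that stand apart, SP1L4 (3.51, adjusted p = 0.0618) and OSM34 (adjusted p = 0.0906) did not pass in Col-0, where 11 of 29 named genes kept their call, against 33 of 33 in atg5. In atg5 AT1G23205 (3.21 ± 0.48), EXO (3.13 ± 0.44) and THI2.2 (3.11 ± 0.45) were higher, and AT1G62760 (-5.69 ± 0.71), AT4G16260 (-5.30 ± 0.56) and the carboxylesterase gene AT1G68620 (-4.76 ± 0.72) lower.

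Of the 16 autophagy genes, 3 were lower on low nitrate in Col-0, ATG8F (-1.15 ± 0.26), ATG8D (-0.93 ± 0.21) and ATG8I (-0.85 ± 0.21), and 11 in atg5, with ATG8H at -2.78 ± 0.44, and 0 were higher. The list was lower in Col-0 (adjusted p = 0.00157, and adjusted p = 0.47 with an estimated correlation) and in atg5 (adjusted p = 2.85e-09, and adjusted p = 0.277 with an estimated correlation). Of 5 protease genes 3 were lower in Col-0, CATHB3 (-1.7), CATHB2 (-1.19) and SCPL49 (-1.16), and 2 in atg5, CATHB3 (-2.20) and CATHB2 (-0.82, adjusted p = 0.0604 without the culture block). Their list was lower in Col-0 (adjusted p = 0.000739, and adjusted p = 0.361 with an estimated correlation) and atg5 (adjusted p = 0.0241, and adjusted p = 0.555 with an estimated correlation). Without the 2 arrays that stand apart 0 autophagy and 0 protease genes passed in Col-0, and 12 autophagy and 4 protease genes were lower in atg5. These directions are those of low nitrate at 30 days. In atg5 mean log2 ATG8H was 8.13 there, 11.73 on low nitrate at 60 days and 10.91 on high nitrate. ATG8A lay at 9.61, 11.94 and 11.29, so both orders turned at 60 days. In Col-0 at 60 days ATG8H (7.69) stayed below high nitrate (8.44), and ATG8A (10.4) lay near it (10.37).

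UGT74B1 was higher on low nitrate in Col-0 (1.29 ± 0.31) and UGT74C1 in atg5 (1.33 ± 0.32), and the glucosinolate list was higher in Col-0 (adjusted p = 0.0383, and adjusted p = 0.559 with an estimated correlation). UGT74B1 did not pass without the 2 arrays that stand apart (1.16, adjusted p = 0.135). UGT74B1 (adjusted p = 0.0581) and that list (adjusted p = 0.0633) did not pass without the culture block, nor did the list after quantile normalization (adjusted p = 0.0539). In atg5 SARD4 (-1.62), WRKY6 (-1.68), PPDK (-1.52), PDF1.2 (-2.81) and ERDJ3B (-0.99) were lower, and in Col-0 0 members of the salicylic acid, senescence, jasmonate and ER lists changed. The salicylic acid list was lower in atg5 (adjusted p = 0.0413, and adjusted p = 0.571 with an estimated correlation), though not without the culture block (adjusted p = 0.0528). HHO2 was lower in Col-0 (-1.38 ± 0.38), though not after quantile normalization (adjusted p = 0.0685), and NRT2.5 did not pass in Col-0 (0.92) or atg5 (-1.19). The root marker BGLU23 was higher on low nitrate in Col-0 (1.59 ± 0.36, and 1.34 with adjusted p = 0.134 without the 2 arrays) and atg5 (2.11 ± 0.36). In both genotypes 0 genes changed among those for flavonoids, photosynthesis, the proteasome and cold and dehydration.

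Under limma's test 453 probe sets were higher and 647 lower on low nitrate in Col-0, and 700 and 999 in atg5. The 2 genotypes, with no array in common, shared 260 higher (23.2 expected) and 363 lower (47.4 expected). In Col-0 the count was 304 and 2120 without the low-nitrate arrays of cultures 1 and 2, 512 and 74 without the high-nitrate ones, and 332 without the 2 arrays that stand apart. In atg5 it was 860 and 0 without the low-nitrate arrays of cultures 1 and 2 and 0 without the high-nitrate array of culture 2, and 0 of 33 named genes kept their call throughout, against 5 of 29 in Col-0. Without the 2 arrays that stand apart, which are in neither atg5 group, it was 2476 in atg5. With low nitrate at 60 days in place of 30 days the count was 73 in Col-0 (23 higher, 50 lower) and 9 in atg5 (3 higher, 6 lower). The effects of age and nitrate in Col-0 share the 30-day low-nitrate arrays and correlated at r = -0.747 (simulated unchanged arrays -0.501, covariance -0.505 against -0.0752), and at -0.310 and -0.387 across cultures that share no array.

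The difference between atg5 and Col-0 in the nitrate comparison gave 0 probe sets by limma's test, with 784 under an unadjusted p of 0.05. The named genes with the smallest p were AT1G62760 (-5.56 ± 1.01), AT5G40690 (-4.13 ± 0.77) and AT3G47540 (-1.93 ± 0.36), each with an adjusted p = 0.448. The count was 248 without the 30-day Col-0 array of culture 2 and 2 without the high-nitrate Col-0 array of culture 2. The autophagy list was lower (median -0.62, adjusted p = 9.95e-06, and adjusted p = 0.361 with an estimated correlation) and the photosynthesis list higher (median 0.59, adjusted p = 0.00226, and adjusted p = 0.555 with an estimated correlation) on low nitrate in atg5 relative to Col-0. The flavonoid list was also higher (median 2.38, adjusted p = 0.0137, and adjusted p = 0.555 with an estimated correlation), and 0 members of the 3 lists passed over all genes. The photosynthesis median was 0.36 without the 2 arrays that stand apart. These directions hold for low nitrate at 30 days. With 60 days in its place 0 probe sets passed, and the direction turned for ATG8H and AT3G47540. Mean log2 ATG8H in atg5 and Col-0 was 11.73 and 7.69 on low nitrate at 60 days, and 10.91 and 8.44 on high nitrate. AT3G47540 lay at 11.34 and 7.12, and at 10.46 and 8.57.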

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

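The weighing of explanations in this part rests on tests chosen only after the results were seen, while the interaction tests and the list tests were planned.

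Several genes changed with age by different amounts in the mutants and in Col-0, by a direct test of the difference, in which 22 probe sets passed for atg5 and 1 for atg9. AT2G15220 (5.71, and 4.59 with 32 added), AT5G40690 (5.47), AT5G38900 (5.07), AT3G47540 (4.26) and ATG8H (4.04) had a higher log2 change in atg5 than in Col-0 and AT1G68490 (-1.95) a lower one, and for AT3G47540 the change was 2.99 higher in atg9. In Col-0 itself AT3G47540 fell with age (-1.65), AT1G68490 rose (1.56) and the other 4 did not pass. In atg9 AT3G47540 rose with age by 1.34, AT2G15220 by 3.42 (2.53 with 32 added), AT5G40690 by 4.61, AT5G38900 by 3.82 and ATG8H by 1.87. AT1G68490 did not pass in atg9 (0.31). With the 2 arrays that stand apart left out, 1 of the 7 calls of a difference from Col-0, AT3G47540 in atg5 (4.51), was kept. The others lay at 5.5, 5.02, 4.46, 3.68 and -1.74 for AT2G15220, AT5G40690, AT5G38900, ATG8H and AT1G68490 in atg5, and at 2.98 in atg9. The mutants themselves differed in 1 probe set at 30 days and 1 at 60 days, in both cases 264113_at. The fitted differences of atg9 from atg5, -4.78 and -8.11, do not measure its size, because the atg9 signals of 1.9 to 6.9 lay under the lower quartile of every array. The difference with 32 added, a damped estimate of the size, was -2.31, which did not pass (adjusted p = 0.27), and -4.47. It was lower in both atg9 arrays at each age and has no gene name here.

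Gene lists differed between genotypes in the change with age. For atg5 these were autophagy (adjusted p = 3.83e-09), salicylic acid and defence (adjusted p = 0.02), both higher, and abscisic acid, cold and dehydration (adjusted p = 0.0276), lower. None passed with an estimated correlation (adjusted p = 0.277 with an estimated correlation for the first and adjusted p = 0.555 with an estimated correlation for the other 2). For atg9 they were autophagy (adjusted p = 1.31e-05) and salicylic acid and defence (adjusted p = 0.0106), higher, and photosynthesis (adjusted p = 0.0154) and cold and dehydration (adjusted p = 0.0277), lower. These 4 did not pass either (adjusted p = 0.361, 0.555, 0.571 and 0.555 with an estimated correlation). By median both lists lay below 0 for atg9 in culture 1 alone, the culture of the Col-0 array with the raised lower quartile. The photosynthesis median was -1.07 in culture 1, 0.29 in culture 2 and -0.15 without the 2 arrays that stand apart, and that of cold and dehydration was -1.86, 0.03 and -0.67. For atg5 the cold and dehydration median of -2.13 was -3.09 in culture 1, -1.07 in culture 2 and -1.14 without the 2 arrays. In the nitrate comparison, made with low nitrate at 30 days, autophagy (adjusted p = 9.95e-06) was lower on low nitrate in atg5 relative to Col-0. Photosynthesis (adjusted p = 0.00226), flavonoids (adjusted p = 0.0137) and cold and dehydration (adjusted p = 0.0391) were higher there. Of these 4, 0 passed (adjusted p = 0.361, 0.555, 0.555 and 0.571 with an estimated correlation). After quantile normalization the cold and dehydration list did not pass for atg9 (adjusted p = 0.052) or for nitrate (adjusted p = 0.0834).

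At 60 days 795 probe sets differed from Col-0 in atg5 and 6 in atg9. The atg5 array of culture 1 had an actin 3′/5′ ratio of 9.05, but without it 196 probe sets still passed, against at most 4 in atg9 with 1 array left out, which argues against lower RNA quality as the whole cause. A smaller change of the same probe sets in atg9 may account for the rest, since the slope of atg9 on atg5 across cultures that share no array was 0.490 and 0.646. The test between the mutants gave 1 probe set, so a difference of the mutants gene by gene was not shown. An effect of RNA quality on part of the 795 stays open. The Col-0 arrays enter both comparisons alike, so they alone do not account for the difference in counts. They can raise the correlation of the 2 effects, since r was 0.501 in unchanged simulated arrays. Across cultures that share no array r was 0.574 and 0.760, which argues against the shared arrays as its whole source.

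The high-nitrate arrays lay nearer to low nitrate at 60 days than at 30 days, with 73 probe sets in Col-0 and 9 in atg5 against 1100 and 1699. Measured from 30-day low nitrate, the slope of the high-nitrate change on the change with age was 0.666 to 0.879 over 2 genotypes and 2 orders of the cultures. A harvest of the high-nitrate plants at 60 days, as the source and description fields give it, could produce these values. A nitrate effect at 30 days that resembles ageing could produce them too. The 2 cannot be told apart, because the labels give 2 ages for every high-nitrate array.

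At 30 days 0 probe sets differed between atg5 and Col-0, where the Col-0 array of culture 1 had a raised lower quartile. That array could have hidden an effect as large as the 795 probe sets at 60 days. The 30-day atg5 change was therefore taken from culture 2, which lacks it. Its slope on the 60-day change, taken from each culture in turn, was 0.140 and 0.133. Both slopes lie below the 0.5 set as the bound, which argues against an effect of that size in the 60-day pattern. The slope cannot detect an effect on other probe sets, so such an effect at 30 days stays open. A smaller effect stays open too, since in simulated arrays 8 of 50 probe sets changed by 1 and 36 of 50 changed by 2 were recovered. Those arrays were simulated with equal noise in all groups, so recovery in the real comparison may be lower.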

How the results depend on the processing

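The fit without the 2 arrays that stand apart was chosen after the data were seen, and the other alternatives were planned. Without the replicate block the count was 36 for atg9 at 60 days, 38 for the age by atg5 interaction and 0 for the age by atg9 interaction, and the other 12 stayed within 1.5 times. After quantile normalization the counts were 61 (60 higher, 1 lower) for atg9 at 60 days, 63 (60 and 3) for atg5 on high nitrate, 3 for atg9 against atg5 at 60 days, 123 (110 and 13) for age by atg5 and 0 for age by atg9. It changed the share that rose with age from 59.8% to 49.2% in Col-0 and from 61.0% to 48.1% in atg9. The median of all probe sets moved from 0.125 to -0.026 for age in atg9 and from 0.0033 to -0.061 for age by atg9. For atg9 at 60 days the share higher went from 83.3% to 98.4%, for atg9 against atg5 at 60 days from 0% to 33.3%, and for age by atg9 the 1 call, which was higher, was lost and no share remained. With no filter the counts were 28 for atg9 at 60 days and 56 for age by atg5. With log2 of the signal plus 32 they were 56 for atg9 at 60 days, 62 for atg5 on high nitrate, 0 for atg9 against atg5 at 30 days, 86 for age by atg5 and 0 for age by atg9. Without the trend they were 3, 14, 1 and 0 for atg9 at 60 days, atg5 on high nitrate, age by atg5 and age by atg9. With low nitrate at 60 days in place of 30 days they were 73 in Col-0 and 9 in atg5. The cause was not tested.

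With the 2 arrays that stand apart left out, the counts were 0 for atg9 at 30 days, 232 for atg5 at 60 days, 47 for atg5 on high nitrate, 369, 2016 and 4078 for age in Col-0, atg5 and atg9, 332 and 2476 for nitrate in Col-0 and atg5, and 1 and 0 for age by atg5 and by atg9. Neither array is part of the comparisons of atg5 on high nitrate, of nitrate in atg5 and of age in atg9. Their log2 changes were therefore the same in both fits. Only the spread estimated over all groups differed, and with it the p-values. For the other comparisons the cause was not tested. The correlation of the atg5 and atg9 effects at 30 days was 0.772 with shared Col-0 arrays, and reversed to -0.0474, or fell to 0.00451, across cultures that share none. At 60 days it was 0.871, and 0.574 and 0.760 across cultures.

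Leaving out 1 array leaves a lone array that is assumed to vary like the other groups. The counts then ran from 0 to 766 for atg5 and 0 to 874 for atg9 at 30 days, 100 to 1647 for atg5 and 2 to 4 for atg9 at 60 days, 0 to 43 for atg5 on high nitrate, 0 to 0 and 1 to 144 for atg9 against atg5 at 30 and 60 days. For age they ran from 67 to 2546 in Col-0, 1017 to 3271 in atg5 and 794 to 1599 in atg9, and for nitrate from 74 to 2120 in Col-0 and 0 to 1237 in atg5. For age by atg5, age by atg9 and nitrate by atg5 they ran from 1 to 689, 0 to 337 and 0 to 248. Of the values of named genes with 1 array left out, 568 kept direction and side of the threshold, 406 fell below it and 10 rose above it.

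For the named genes 220 values kept their side without the block and 14 fell below the threshold, as did 11 after quantile normalization and 3 with 32 added. Of 46 list tests past the threshold, 43 passed without the block, 36 after quantile normalization and 0 with an estimated correlation. Signals near background limit the changes of dim probe sets. With 32 added the change of AT1G57630 with age in Col-0 was 1.49 and did not pass.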

Other observations

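The 8 gene families and organelle genomes in this part were chosen and tested after the data were seen, and no explanation for them was tested. Expansins, xyloglucan-modifying enzymes and endoglucanases, which loosen or remodel the cell wall, fell with age in 10 of 11 cases in atg5, in 3 in atg9 and in 2 in Col-0. In the fit lacking the 2 arrays that stand apart, 2 fell in atg5, 5 in atg9 and 1 in Col-0, so the order of the mutants turned. GH9B13 fell by 3.47 ± 0.64 on the log2 scale in atg5 and XTH16 by 1.61 ± 0.33, and in Col-0 they changed by -2.79 ± 0.64 (-2.26 and adjusted p = 0.132 without the 2 arrays) and -2.06 ± 0.33. The list was lower with age in atg5 (adjusted p = 4.44e-05, and adjusted p = 0.751 with an estimated correlation). In atg5 at 60 days the family median against 30 days was -2.77 in culture 1, whose array had an actin 3′/5′ ratio of 9.05, and -1.29 in culture 2. Against Col-0 at 60 days 4 of the 11 were lower in atg5, EXPB3 (-2.32), GH9B8 (-1.89), GH9C2 (-1.85) and EXPA4 (-1.64), and 0 passed without those arrays.

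Of 8 tubulin and actin genes 2 fell with age in Col-0, 5 in atg5 and 4 in atg9, and 1, 2 and 4 without the 2 arrays that stand apart. The atg5 median was -1.62 in culture 1, the culture of the array with the high actin ratio, and -0.82 in culture 2, and TUB5 (-0.90, adjusted p = 0.086), TUB9 (-0.69, adjusted p = 0.103) and TUA6 (-0.80, adjusted p = 0.11) did not pass in atg5 without the 2 arrays. ACT11 changed by -2.74 ± 0.27, -1.95 ± 0.27 and -2.64 ± 0.27, and TUB7 by -1.29 ± 0.23, -1.49 ± 0.23 and -1.67 ± 0.23, and TUB7 did not pass in Col-0 without the 2 arrays (-1.16, adjusted p = 0.0577). The list was lower in Col-0 (adjusted p = 0.00394), atg5 (adjusted p = 0.00394) and atg9 (adjusted p = 0.000918), with an adjusted p = 0.751 with an estimated correlation in each.

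Of 69 plastid-encoded genes 20 fell with age in atg5, 2 in atg9 and 0 in Col-0. In atg5 rpl14 changed by -2.43 ± 0.46, psbI by -1.67 ± 0.35 and rpl33 by -3.21 ± 0.85, and in atg9 psbI changed by -1.09 ± 0.35 and psbK by -1.52 ± 0.49. The list was lower with age in atg5 (adjusted p = 0.0001, and adjusted p = 0.826 with an estimated correlation), with medians of -1.26 in culture 1 and -1.14 in culture 2, and 10 passed without the 2 arrays that stand apart. In atg9 the median with age was -1.30 in culture 1 and 0.11 in culture 2. At 30 days the median in atg5 against Col-0 was 0.86 with 0 passing, at 0.42 in culture 1, 1.19 in culture 2 and 1.53 without the 2 arrays. The median of low against high nitrate in Col-0 was -0.13 in culture 1, whose 30-day array had the raised lower quartile, and -2.32 in culture 2. Of 7 mitochondrion-encoded genes cox1 rose with age in atg5 and atg9 (1.64 ± 0.38 in each). After removal of the 2 arrays that stand apart, cox1 did not pass in atg5 (1.49, adjusted p = 0.0736), and 0 of the 7 rose in atg5 and 4 in atg9.

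Of 12 cytochrome P450 genes 2 rose with age in Col-0, 3 in atg5 and 3 in atg9, and 0 fell. The rises numbered 0, 4 and 3 without the 2 arrays that stand apart. CYP71B23 rose with age by 2.48 ± 0.63 in Col-0 (1.96 with 32 added), 3.53 ± 0.63 in atg5 and 3.88 ± 0.63 in atg9, and it was higher in atg5 than in Col-0 at 60 days (2.6 ± 0.63), as were CYP71B24 (1.90 ± 0.47) and CYP71B6 (1.40 ± 0.22). Without the 2 arrays that stand apart CYP71B23 lay at 2.8 with age in Col-0 and did not pass (adjusted p = 0.0648), nor did CYP71B24 in atg5 at 60 days, at 2.0 (adjusted p = 0.108). Of 21 UDP-glycosyltransferase genes 4 rose and 1 fell with age in Col-0, 2 rose and 3 fell in atg5, and 5 rose and 2 fell in atg9. UGT71C5 rose in the 3 genotypes (1.16, 1.03 and 1.35), and UGT72E1 (2.23 and 2.19), UGT85A4 (1.66, or 1.33 with 32 added, and 1.49) and UGT72B3 (1.55 and 1.01) in Col-0 and atg9. UGT74B1 fell in the 3 genotypes (-1.11, -1.28 and -1.06), UGT76E11 in atg5 and atg9 (-2.12 and -2) and UGT78D1 in atg5 (-1.27). UGT87A2 rose with age by 2.67 ± 0.37 in atg5 and 1.92 ± 0.37 in atg9, and was higher in atg5 than in Col-0 at 60 days (2.94 ± 0.37). In the fit lacking the 2 arrays 0 of the 21 passed with age in Col-0, UGT71C5 and UGT87A2 rose and 0 fell in atg5, and 6 rose and 2 fell in atg9. Of 7 beta-glucosidase genes 2 fell with age in Col-0, 3 in atg5 and 3 in atg9, 0 rose, and 0, 2 and 3 fell without the 2 arrays. BGLU47 fell with age in Col-0 (-2.29 ± 0.60), atg5 (-3.82 ± 0.60, and -3.22 with 32 added) and atg9 (-2.94 ± 0.60), and BGLU40 did so too (-1.15, -1.33 and -1.23). In Col-0 neither passed without the 2 arrays (-1.82 with adjusted p = 0.163 and -0.99 with adjusted p = 0.0717). Of 7 SWEET sugar transporter genes 0 changed with age in Col-0, 2 fell in atg5 and 1 in atg9, and 0, 1 and 2 fell without the 2 arrays. SWEET17 fell with age in atg5 (-2.72 ± 0.48) and atg9 (-1.92 ± 0.48).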
